A study of Homo sapiens with 9 samples.

How the data were processed

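Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on human blood neutrophils with antibodies against 2 histone marks. H3K4me1 is the monomethylation of lysine 4 of histone H3, a mark found at enhancers whether active or not. H3K27ac is the acetylation of lysine 27, found at active enhancers and active promoters. The 9 samples form 3 sets, each of an H3K4me1 library, an H3K27ac library and an input DNA library. The libraries of a set share the first word of their titles, which is where the pairing of the marks comes from. The sets are called preparations 1, 2 and 3 here, in order of accession. The labels do not say in words that the preparations came from separate people, so p-values of the exact tests between lists measure only the spread between these preparations, which may be technical. The p-values of circular shifts concern the positions of peaks within the lists and not that spread. According to the labels' protocols, neutrophils were separated from mononuclear cells on a density gradient, red cells were lysed, and chromatin was fixed and sheared with micrococcal nuclease and sonication before Illumina sequencing.

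The values analysed were 6 peak lists in broadPeak layout, 1 per ChIP library. The submitters' processing notes name CASAVA 1.8.2, BWA, MACS2 and the genome build hg19, without saying which step each served. The names of the alternative haplotype contigs in the lists are those of hg19. Peak names carry 1 preparation and 1 mark each, so replicates had not been pooled. Whether the matching input served as the control of each list is not given in the sources used here, and no input list was analysed here. Each peak has a fold enrichment ratio that the authors' peak caller assigned, and this value was compared only within a list. Each peak also has a q-value, deposited as −log10 q, whose smallest value in any list lies just above 1, so the lists were called at a q-value of about 0.1. In every list, consecutive autosomal peaks were at least 601 bp apart, so neighbouring enriched stretches had already been joined before the lists were deposited. The lists give no read counts, so the sequencing depth behind each peak is unknown, and a longer list can reflect a deeper or cleaner library as well as more marked chromatin.

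Autosomes were analysed, which hold between 96.8% and 97.6% of the peaks of each list. Sex chromosomes were left out because the cells are human, and peaks on alternative haplotypes and unplaced contigs were counted separately. All interval arithmetic was done in Python 3.11.15 with NumPy 2.4.6, tests used SciPy 1.17.1, and plots used matplotlib 3.10.9. Coordinates are 1-based positions on hg19. No annotation or genome of that build was used here, so regions are given by position only and are not assigned to genes, exons or promoters. For the same reason 2 comparisons, of promoters and of enhancers near genes, for 15 gene lists fixed before the data were examined, were not run.

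Peaks were taken to overlap from 1 shared bp. The list length, the covered length and the median peak width were compared between the marks with a two-sided exact permutation test of 3 against 3 lists, which cannot give a p below 0.1. The agreement of 2 lists was measured with the Jaccard index, the bp in both lists divided by the bp in either. Shares of overlapping peaks and Jaccard indices were set against 1000 circular shifts. In each shift, the peaks of a list moved together by a random distance within the span that peaks occupy on each chromosome, which keeps their widths and their spacing. The smallest p that 1000 shifts can give is 0.001. The Jaccard index of the 2 marks within a preparation was compared with that across preparations over the 6 ways of matching the lists, which cannot give a p below 0.167. The exact sign-flip test of paired differences over 3 preparations cannot give a p below 0.25. Because the libraries of a preparation share a title word, this paired test was run as an alternative.

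Candidate active enhancer regions are bases inside an H3K4me1 peak and an H3K27ac peak of the same preparation, in at least 2 of the 3 preparations, merged and at least 200 bp long. H3K27ac clusters are bases inside H3K27ac peaks of at least 2 preparations, joined when at most 12.5 kb apart and ranked by the H3K27ac length inside. The rule for naming regions was to give the 10 clusters with the most H3K27ac and the 10 widest candidate regions. Alternatives were a stricter q-value, equal numbers of peaks, another overlap minimum, local shifts, joined peaks, other consensus and stitching limits, the paired test and leaving out each preparation. The tests, the alternatives and this rule were fixed before the data were examined. Exceptions, chosen afterwards, are the splits of peaks by recurrence, by fold decile and by width quartile, the shifts behind the fold and width ratios, the widest regions with 1 mark only, the densities by chromosome, the chromosome 19 and H3K4me1 gap analyses, and the alternatives named as such in the closing section. The measures were tested on simulated lists of 6000 and 10000 peaks with 20%, 50% and 80% planted overlap, which were recovered with an error of 0 percentage points. Simulated peaks could overlap only where planted, so this checks the arithmetic alone. Of 40 pairs of unrelated simulated lists, 2 reached a shift p of 0.05 or less. Those peaks had equal widths and evenly random positions. Clustered peaks of varied width, as in the lists analysed, were not simulated, so their shift p-values were not checked.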

Results

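Peaks of 2 histone marks were compared in neutrophils, the phagocytes that make up most of the white cells in human blood, in order to locate active enhancers. The H3K4me1 lists held 87655, 120346 and 88750 autosomal peaks in preparations 1, 2 and 3. The H3K27ac lists held 65152, 41729 and 57362 peaks. Read depth is unknown for every list. The strongest peaks differed in certainty between the marks. The highest −log10 q lay between 37.6 and 51.6 in the H3K27ac lists and between 8.99 and 14.8 in the H3K4me1 lists.

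The first comparison asks how much of the genome carried each mark. H3K4me1 peaks covered 237 ± 34.0 Mb of the autosomes (SD, n = 3) and H3K27ac peaks 93.1 ± 19.8 Mb (SD, n = 3). H3K4me1 covered more in 3 of 3 preparations, by 1.91-fold to 3.87-fold. The H3K4me1 lists were also longer, with 98917 ± 18566 peaks against 54748 ± 11928 (SD, n = 3 each), again in 3 of 3 preparations. Neither difference can pass a threshold of 0.05 with 3 lists per mark, and both gave the smallest possible value (two-sided exact permutation test, p = 0.1, n = 3 per mark). The median peak width was 1016 ± 84.7 bp for H3K4me1 and 855 ± 97.5 bp for H3K27ac (SD, n = 3 each). It was larger for H3K4me1 in 2 of 3 preparations, by a mean of 161 bp (two-sided exact permutation test, p = 0.2, n = 3 per mark). This difference was 251 bp without preparation 2, 77.5 bp without preparation 3, 486 bp with peaks within 2 kb joined, 1188 bp with equal numbers of peaks and 6187 bp with −log10 q of at least 5. The order of the marks in list and covered length turned at that stricter threshold, where the lists held 2343, 470 and 1180 H3K4me1 peaks and 9789, 8470 and 7916 H3K27ac peaks. The difference in list length, 44169 peaks, was 26946 without preparation 2 and 15928 with peaks within 2 kb joined.

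The second comparison asks whether the preparations carried each mark in the same places. They did so far beyond the circular shifts for both marks. H3K4me1 lists shared a mean Jaccard index of 0.610 (range of 3 pairs 0.574 to 0.647), against 0.0520 after circular shifts. H3K27ac lists shared 0.506 (0.488 to 0.518), against 0.0193 after shifts. Every one of the 6 pairs exceeded all of its 1000 shifts (p = 0.001 each by random circular-shift permutation, the smallest these can give). Local shifts of 100 kb to 1 Mb gave higher means, 0.0888 for H3K4me1 and 0.0322 for H3K27ac. Sequence in which no peak can be called was not left out of the shifts. Of the bases with H3K4me1 in any preparation, 47.4% carried it in all 3 and 30.0% in a single preparation. At −log10 q of at least 5 the H3K4me1 index was 0.295. For H3K27ac, 36.7% of bases were shared by all 3 preparations and 44.3% belonged to a single one.

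Strong peaks recurred in nearly all cases and weak peaks often did not. Among H3K27ac peaks in the top fold enrichment decile of each list, 99.2%, 99.6% and 99.6% overlapped a peak in both other preparations. In the bottom decile, the shares were 7.89%, 36.5% and 11.6%. The corresponding H3K4me1 shares were 97.9%, 93.0% and 98.6% at the top and 41.8%, 10.5% and 24.0% at the bottom. The deciles were not matched for peak width or set against shifts, so strength and width are not told apart here. The longest list of each mark held the largest share of peaks found in neither other preparation. These made up 39.7%, 9.04% and 35.3% of the H3K27ac lists and 11.7%, 30.8% and 11.7% of the H3K4me1 lists.

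The third comparison asks how far the marks coincide, since a region with both is a candidate active enhancer. In the lists as called, most H3K27ac peaks overlapped an H3K4me1 peak and most H3K4me1 peaks overlapped no H3K27ac peak. Of H3K27ac peaks, 80.8% ± 11.2 (SD, n = 3) overlapped an H3K4me1 peak of the same preparation, against 14.3% after shifts. Of H3K4me1 peaks, 35.2% ± 9.46 (SD, n = 3) overlapped H3K27ac, against 7.30% after shifts. Each of the 6 lists exceeded all of its 1000 shifts (p = 0.001 each by random circular-shift permutation, the smallest these can give), and the shares were 4.44 to 5.95 times the mean of the shifts. The H3K27ac share was 71.8% in preparation 1 (95% Wilson interval 71.4% to 72.1%), 93.4% in preparation 2 (93.1% to 93.6%) and 77.4% in preparation 3 (77.0% to 77.7%). These intervals cover counting error only and treat peaks as independent. The H3K27ac share was above the H3K4me1 share in 3 of 3 preparations, by a mean of 45.6 ± 20.6 percentage points (two-sided exact sign-flip test, p = 0.25, n = 3, the smallest it can give). Each overlap counts towards both shares while the lists differ in length, so the order of the shares depends in part on which list is longer. The order turned at −log10 q of at least 5, with 12.4% for H3K27ac and 69.3% for H3K4me1, against 1.26% and 7.19% after shifts. The H3K4me1 share crossed 50% in some alternatives and was 16.0% when at least 50% of the peak had to be covered, 19.4% by midpoint, 53.3% in recurrent peaks and 56.9% with equal numbers of peaks, where the H3K27ac share was 74.99% and the shares lay closer together.

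**Figure D1:**
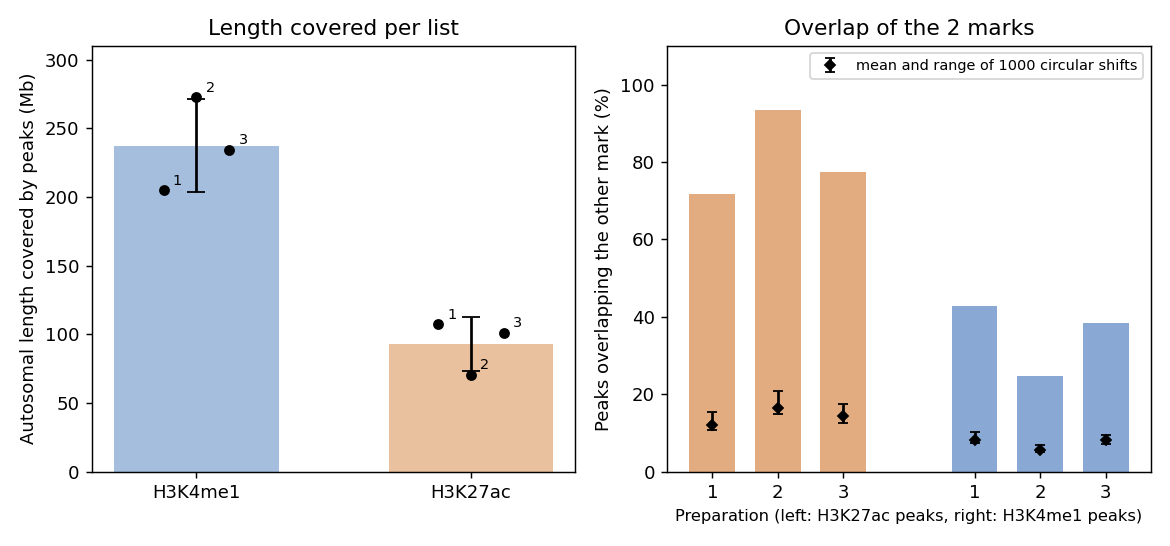
Left, the autosomal length covered by peaks in Mb, with bars for the mean of 3 lists, error bars for the SD and numbered points for the preparations. Right, the percentage of H3K27ac peaks (orange) and H3K4me1 peaks (blue) that overlap the other mark in the same preparation, with black diamonds and whiskers for the mean and range of 1000 circular shifts; the H3K27ac bars lie between 71.8% and 93.4% and every bar stands above its shifts.

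H3K27ac peaks that overlapped an H3K4me1 peak by at least 1 bp were wider and slightly stronger than those that did not. Their median width was 2.49 ± 0.0821 times that of H3K27ac peaks without H3K4me1 (SD, n = 3), with 1175 against 466 bp in preparation 1. A wider peak meets another list more easily, and after shifts the ratio was 1.45. Their median fold enrichment was 1.13 ± 0.0195 times as high (SD, n = 3), higher in 3 of 3 lists and above the highest of 200 shifts in any list, 1.07. In the widest quartile of H3K27ac peaks, 97.4%, 99.9% and 98.5% overlapped H3K4me1 in preparations 1, 2 and 3, against at most 22.5% on average after shifts. In the narrowest quartile, the shares were 48.9%, 84.3% and 58.3%. Relative to the shifted mean, these shares were 5.38, 6.73 and 5.31 times in the narrowest quartile and 5.72, 4.43 and 4.93 times in the widest. The ratio was higher in the narrowest quartile in preparations 2 and 3. Shares in the widest quartile lay close to 100%, which caps their ratio. The order therefore does not show which quartile follows H3K4me1 more closely. The fold ratio in the widest quartile was 1.35, 1.19 and 1.41, where the highest shifts gave 1.04, 1.03 and 1.06. It rests on the few peaks of that quartile outside H3K4me1, fewest in preparation 2, where 99.9% overlapped. In the narrowest quartile it was 1.02, 1.00 and 1.02, which in preparation 2 lay within the range of the shifts. The width ratio was 1.49 when scored by the midpoint of the peak and 3.76 with peaks within 2 kb joined. By midpoint the fold ratio was 1.04, and neither midpoint ratio was set against shifts.

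Peaks found in more preparations overlapped the other mark more often, and they were also wider. H3K27ac peaks found in both other preparations overlapped H3K4me1 in 96.3% ± 1.15 of cases (SD, n = 3). Those found in 1 other preparation did so in 82.5% ± 5.90, and those found in neither in 55.9% ± 16.0. H3K4me1 peaks found in both other preparations overlapped H3K27ac in 53.3% ± 4.59 of cases, those found in 1 other in 9.46% ± 1.45 and those found in neither in 3.97% ± 1.61 (SD, n = 3 each). Median widths of recurrent H3K27ac peaks were 2051, 1406 and 1894.5 bp, against 468, 386 and 451 bp for peaks of a single preparation. For H3K4me1 they were 1471, 2249 and 1878 bp, against 430, 473 and 416 bp. Set against shifts, the share of recurrent H3K27ac peaks was 5.93 times the shifted mean and that of all H3K27ac peaks 5.67 times, and the H3K4me1 values were 6.09 and 4.83 times. Peaks of a single preparation were not set against shifts.

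**Figure D2:**
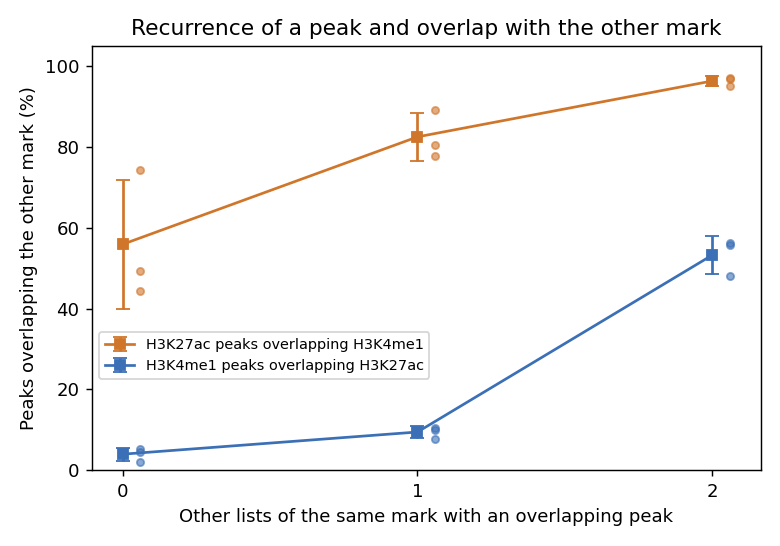
The vertical axis gives the percentage of peaks that overlap the other mark in the same preparation, and the horizontal axis the number of other lists of the same mark with an overlapping peak. Squares with error bars are the mean and SD of 3 preparations and dots are the preparations; H3K27ac peaks (orange) go from 55.9% to 96.3% and H3K4me1 peaks (blue) from 3.97% to 53.3%.

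The fourth comparison asks whether the marks of a preparation match each other better than those of different preparations. By the Jaccard index no such match was found, but the index cannot decide the question. The mean Jaccard index of H3K4me1 with H3K27ac was 0.296 within a preparation and 0.302 across preparations. Of the 6 ways to match the lists, the real one ranked near the bottom (one-sided exact permutation test, p = 0.833, where 0.167 is the smallest possible). The difference of -0.00637 was small beside the range of single pairs, 0.217 to 0.363, and its sign turned without preparation 1, to 0.00265. Lists of unequal covered length cannot reach a high index. Preparation 2 paired the H3K4me1 list with the most covered length (273 Mb) with the H3K27ac list with the least (70.6 Mb), which limits its index. The test therefore cannot tell a missing match from the effect of list lengths.

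Candidate active enhancers were then defined by both marks. Promoters could not be removed without gene positions, so the regions may include sequence at or beside active promoters. In single preparations 52243, 43382 and 50750 intervals held both marks, covering 74.6 ± 11.5 Mb (SD, n = 3). The consensus of at least 2 preparations comprised 38246 regions of 200 bp or more, covering 67.4 Mb with a median width of 929 bp. Of these, 27452 (71.8%) contained bases with both marks in all 3 preparations, and 2592 were over 5 kb wide. Counting only bases marked in all 3 preparations gave 26662 regions, and a threshold of −log10 q of at least 5 gave 894. Of the 239.6 Mb that carried either mark in at least 2 preparations, 29.5% carried both, 66.3% H3K4me1 alone and 4.22% H3K27ac alone. By length, 87.5% of consensus H3K27ac lay inside consensus H3K4me1, and 30.8% of consensus H3K4me1 lay inside consensus H3K27ac.

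The candidate regions were unevenly spread. This spread was not set against the positions of genes or promoters, so it is not a distribution of enhancers alone. Across the autosomes there were 13.7 regions per Mb of the span that peaks occupy. Chromosome 19 had the most regions for its length, 31.9 regions per Mb, followed by chromosome 22 with 28.4 and chromosome 17 with 27.6. Chromosome 4 had the lowest, 7.05, with chromosome 13 at 7.08 and chromosome 18 at 7.39. Chromosomes 17, 19 and 22 had the highest length with both marks per Mb in each of the 3 preparations. On chromosome 22 it was 63.9, 50.6 and 76.6 kb per Mb in preparations 1, 2 and 3. On chromosome 19 it was 60.7, 49.7 and 97.8 kb per Mb, above chromosome 22 in preparation 3 only, and on chromosome 4 it was 14.1, 9.45 and 11.7 kb per Mb. The H3K27ac list of preparation 3 had 6.90% of its peaks on chromosome 19, against 3.24% and 4.45% in preparations 1 and 2.

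**Figure D3:**
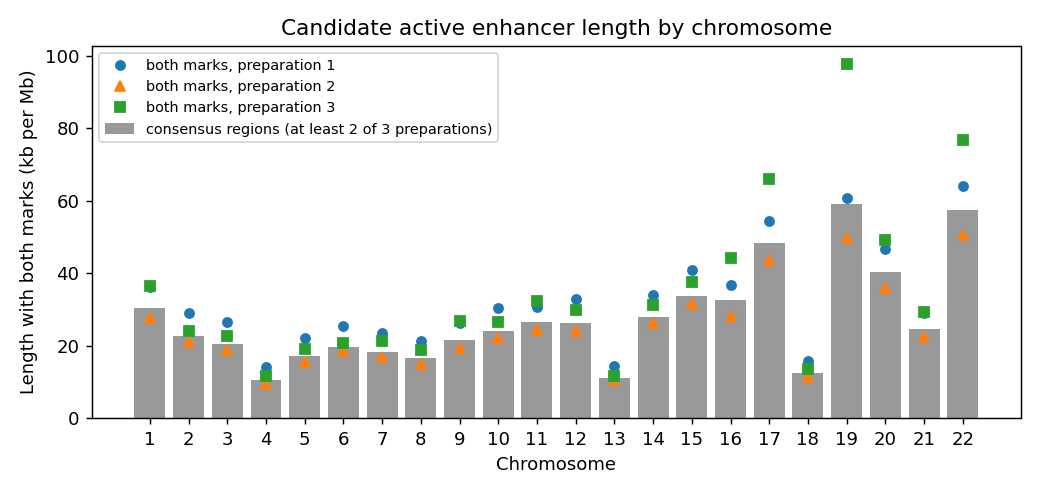
Length with both marks, in kb per Mb of the span that peaks occupy, for each autosome. Grey bars are the consensus regions and symbols the single preparations; chromosomes 17, 19 and 22 stand highest, and preparation 3 reaches 97.8 kb per Mb on chromosome 19.

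The widest candidate regions carried both marks over most of their length in every preparation. The 10 widest measured 41.7 to 59.3 kb, and each single preparation carried both marks over 87.3% to 100% of each. High values follow in part from the definition, by which every base carries both marks in at least 2 of the 3 preparations. The widest was on chromosome 8 from 27183889 to 27243223, with both marks over 100%, 97.6% and 98.4% of its length in preparations 1, 2 and 3. The next were on chromosome 11 from 48018028 to 48074601 (56.6 kb) and on chromosome 10 from 14578879 to 14632507 (53.6 kb). A region of 48.5 kb lay on chromosome 20 from 47360188 to 47408647, and another of 48.4 kb on chromosome 14 from 69382778 to 69431184. The remaining 5 were on chromosome 11 from 118071398 to 118118727, chromosome 16 from 28145057 to 28187581, chromosome 15 from 77274297 to 77316789, chromosome 5 from 169700681 to 169742607 and chromosome 17 from 75429980 to 75471704.

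Large acetylated domains were described as clusters of H3K27ac peaks. The 80.8 Mb of H3K27ac shared by at least 2 preparations fell into 16728 clusters, of which 8833 were a single uninterrupted interval. The median H3K27ac length per cluster was 1820.5 bp. The length was concentrated in few of the 16728 clusters. The top 5% (836 clusters) held 39.6% of it, and 160 clusters held over 50 kb each. The largest lay on chromosome 2 from 70120563 to 70371464, with 174 kb of H3K27ac in a span of 251 kb, and 173, 153 and 196 kb in preparations 1, 2 and 3. The second lay on chromosome 14 from 92848894 to 93152899 with 162 kb, and the third on chromosome 9 from 91965187 to 92174313 with 149 kb. Next came chromosome 8 from 131161681 to 131371621 (137 kb), chromosome 10 from 73447602 to 73651702 (128 kb) and chromosome 18 from 9646013 to 9871164 (127 kb). The last 4 of the top 10 were on chromosome 22 from 36721642 to 36890156 (121 kb), chromosome 20 from 47291375 to 47449917 (110.5 kb), chromosome 12 from 104850312 to 105095894 (108 kb) and chromosome 6 from 42219787 to 42422642 (108 kb). Consensus H3K4me1 covered between 71.0% and 99.3% of these 10 spans. Preparation 2, with the shortest H3K27ac list, had the least H3K27ac in 9 of the 10. The cluster on chromosome 20 contained 1 of the 10 widest candidate regions, and the other 9 regions lay outside the top 10 clusters. At −log10 q of at least 5 there were 6894 clusters.

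**Figure D4:**
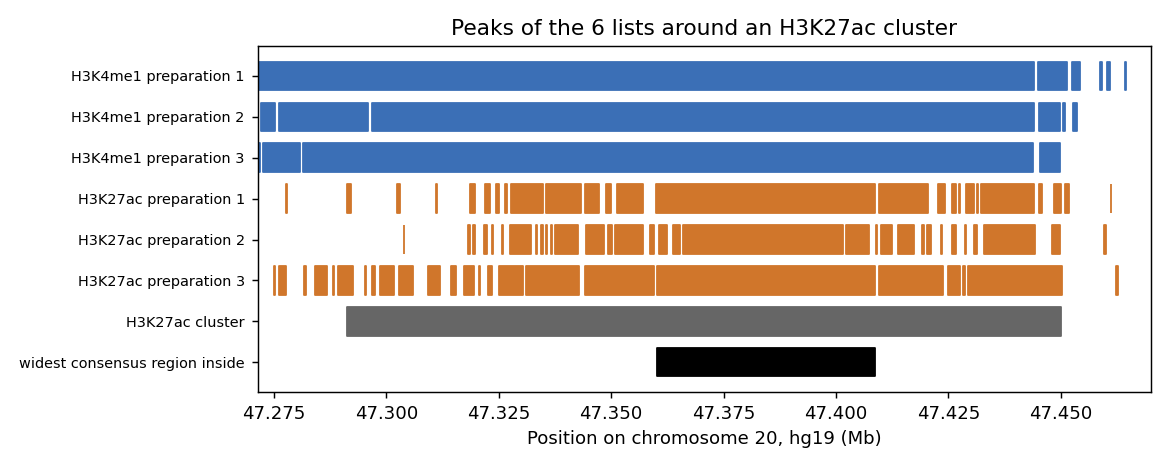
Map of chromosome 20 around the cluster from 47291375 to 47449917 (hg19, Mb on the horizontal axis, with 20 kb on either side). Each row shows the peaks of 1 list, H3K4me1 in blue and H3K27ac in orange. The cluster is in grey and the 48.5 kb candidate region in black. Consensus H3K4me1 covers 99.3% of the cluster and consensus H3K27ac 69.7%.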

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

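Of the tests in this part, the comparison with H3K4me1 on chromosome 19 was chosen after its values had been seen. Peaks on contigs outside the comparisons above are listed first, because the comparisons did not use them. On the alternative haplotypes of chromosome 6 the 3 H3K27ac lists held 1203 peaks and the 3 H3K4me1 lists 456. On other alternative haplotypes they held 172 and 407 peaks, and on unplaced or unlocalised contigs 147 and 149. The only bar these counts were set against was the limit of 3 that a count of 0 allows, which is no background level, and no control list was used here.

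The H3K27ac list of preparation 3 was rich in peaks on chromosome 19, which held 6.90% of its autosomal peaks against 3.24% and 4.45% in preparations 1 and 2. The excess over the mean of the other lists was 3.06 percentage points, in a chromosome and a list picked because they stood out, and the spread between libraries was not tested. Peaks cut into more pieces cannot account for it, since chromosome 19 also held 7.59% of the covered length in that list, against 3.75% and 4.79%. The H3K4me1 list of preparation 3 showed no such excess, with 4.41% of peaks on chromosome 19 against 5.37% and 4.48% in preparations 1 and 2. That comparison was picked with its values known and rests on 1 list. A shift shared by both libraries of the preparation, perhaps unequal between the marks, therefore stays open. The excess may come in part from weak peaks. With −log10 q of at least 5 it shrank to 0.242 times its size (95% bootstrap interval 0.156 to 0.349 over 1 Mb blocks, without the spread between libraries), or 0.739 points. The chromosome 19 shares were then 4.37%, 5.44% and 5.65% in preparations 1, 2 and 3. The excess thus shrank both by a fall in preparation 3 and by a rise in preparations 1 and 2. Base composition and a biological difference between preparations were not tested and stay open.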

How the results depend on the processing

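Alternatives that joined peaks within 2 kb, used peak midpoints or kept only recurrent peaks were chosen after seeing the data. Of 106 alternative values for 12 results, 3 reversed and 12 moved beyond a margin. Only the counts and the fold and width ratios had a margin. Results with a test were judged by direction and by the 0.05 threshold alone, so changes in their size were not counted. At −log10 q of at least 5, the H3K27ac share fell from 80.8% to 12.4% and the H3K4me1 Jaccard index from 0.610 to 0.295. Neither was counted as moved. The exact tests of 3 lists per mark cannot pass 0.05, so their p-values say nothing of stability. Joining peaks within 500 bp moved nothing, because peaks were at least 601 bp apart, and is no test of stability. A −log10 q of at least 5 reversed the H3K4me1 minus H3K27ac difference in list length to -7394 peaks and in covered length to -18.8 Mb, and it gave 894 candidate enhancer regions, 6894 clusters, a fold ratio of 1.02 and a width ratio of 2.62. That threshold holds few H3K4me1 peaks. The fold ratio was 1.08 with at least 50% of the peak covered, 1.04 by midpoint and 1.20 with peaks within 2 kb joined. The width ratio was 1.76 with 50% covered, 1.49 by midpoint, 2.65 with equal numbers of peaks, 2.82 in recurrent peaks and 3.76 with peaks within 2 kb joined. For these shifts the cause was not tested. Leaving out each preparation put the difference between same and different preparations between -0.0215 and 0.00265. With the preparation as a replicate block, the paired test of the difference of 44169 peaks gave an exact p = 0.25, the smallest possible, and the block changed no call. Lists of 1 preparation matched no better than others by Jaccard index, which unequal covered lengths also limit. The block therefore rests on the shared title word. The shares of overlapping peaks and the Jaccard indices stayed above their shifts under every alternative. Against local shifts of 100 kb to 1 Mb, the shares were 3.58 times (H3K27ac) and 3.08 times (H3K4me1) the shifted mean, the lowest of any alternative. Equal numbers of peaks gave no difference in list length by construction. The 2 comparisons of genes were not run, without an annotation of the build. Depth is unknown, so a missing peak does not show a missing mark.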

Other observations

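The regions with a single mark and the gaps were chosen after the data were seen, and the tests of the gaps before their results were seen. Many H3K4me1 intervals met no called H3K27ac peak, which does not show that the mark was missing. Of 97133 consensus H3K4me1 intervals, 49794 (51.3%) held no H3K27ac base in any of the 3 lists, and they covered 38.7 Mb. Consensus H3K4me1 intervals without consensus H3K27ac had a median width of 590 bp, against 2891.5 bp for those with it, a contrast not set against shifts. The widest with no H3K27ac in any list was on chromosome 7 from 131038993 to 131060259 (21.3 kb), where H3K4me1 covered 66.6%, 100% and 100% in preparations 1, 2 and 3. The next were on chromosome 15 from 92572213 to 92590155 (17.9 kb) and on chromosome 19 from 48126241 to 48143786 (17.5 kb).

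Few consensus H3K27ac intervals lay outside consensus H3K4me1, while in single lists 71.8%, 93.4% and 77.4% of H3K27ac peaks overlapped H3K4me1, and 12.4% on average at −log10 q of at least 5. Of 46296 consensus H3K27ac intervals, 42411 (91.6%) overlapped consensus H3K4me1, and the other 3885 had a median width of 307 bp, against 1005 bp, which was not set against shifts either. Of those 3885, 2432 (62.6%) lay within 2 kb of H3K4me1, and 1885 met no H3K4me1 peak in any list. The widest of these was on chromosome 6 from 32936721 to 32939676 (2.96 kb), acetylated over 99.8%, 47.1% and 100% of its length in the 3 preparations. Peaks were also called on 7 alternative haplotypes of chromosome 6. Whether any of them repeats this stretch was not examined, so the missing H3K4me1 peak there may not show a missing mark.

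Some short gaps in H3K4me1 held H3K27ac. The limits were set at 500 and 3000 bp, but no gap in the lists was under 601 bp, so shorter dips could not be seen. Gaps within these limits between H3K4me1 peaks at least 1000 bp wide numbered 15720, 22569 and 16047. Their midpoints lay in H3K27ac in 22.7% ± 5.11 of cases (SD, n = 3). This level is no higher than beside the gap: points 500 bp inside the flanking peaks lay in H3K27ac in 26.0% ± 8.68 of cases, a mean difference of -3.33 percentage points (-6.57, 0.782 and -4.21 in preparations 1, 2 and 3), so dense local acetylation may account for the level. Gaps left by chance in peak calling are argued against for the acetylated gaps as a set, since their midpoints were free of H3K4me1 in both other preparations in 68.0% ± 6.57 of cases against 41.9% ± 8.32 for other gaps, 26.1 points more and more in 3 of 3 preparations. A dip of H3K4me1 at acetylated promoters, where methylation of the same lysine is known to go further, is a hypothesis that could not be tested without gene positions.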
